A study of Mus musculus with 6 samples.

How the data were processed

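Droplet single-cell RNA sequencing (10x Genomics) was analysed in 6 mouse samples, 2 from each of 3 groups: naive blood mononuclear cells, and peritoneal cells isolated with Ly6G beads 4 h and 3 days after intraperitoneal zymosan. The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and barcode, unfiltered, over 31053 genes and 6794880 possible barcodes per sample. Per the file headers, Cell Ranger 3.1.0 had made the blood counts and Cell Ranger 3.0.0 the peritoneal counts. The submitters' processing notes name Cell Ranger 1.3, Seurat 4.1.0 and the mm10 genome. The software version differed between blood and peritoneum in every sample, so the comparisons with blood cannot separate tissue, sorting and software.

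The 2 blood files held 1 library. Of 5039 barcodes with at least 500 UMIs in each file, 5036 were shared, and the UMIs per shared barcode correlated at r = 0.999882. The chi-square per gene between the 2 blood files was 0.376, against 234 between the 4 h libraries and 95.1 between the day 3 libraries. The design had assumed 6 independent libraries. Blood was therefore treated as 1 library, read cell by cell from the first file, with the rounded mean of both files as its summed counts, and 5 independent libraries remained. The labels do not state whether replicates are separate mice or pools, so what a spread over 2 libraries covers is unknown. This change and the alternative with both files kept apart were made after the data were examined.

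Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were called cells. Doublets were scored per library with Scrublet (scanpy 1.11.5), and the highest-scoring 0.8% per 1000 called cells were removed, 2.82% to 5.99% of the cells of a library. Scrublet's own threshold had called only 0% to 0.285%. Called cells of all libraries were clustered together on 30 principal components of 2000 variable genes, with 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2), without integration. Barcodes with 10 to 100 UMIs gave the empty-droplet profile, which was read as a measure of free RNA.

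Clusters were named from marker lists of 13 cell classes fixed before the data were examined. A name required at least 3 markers at 10 CPM (UMIs scaled to a common total per library) or more, the highest marker mean, and no other class with more markers among the 10 leading genes. Shallow clusters also needed a marker of their own among these genes. Clusters 2, 4, 7, 8, 9 and 16 were named neutrophil-like with 0 neutrophil markers there. Names end in "-like" because no protein was measured on the cells. Neutrophil-like cells were clustered again, and a subcluster with at least 2 markers of another class among its 10 leading genes was left out. The form of this rule that asked for 1 marker had removed many 4 h cells and was relaxed after this was seen. Rules on small contributions were also set after the data were examined: profiles used libraries with at least 5% of a cluster, fewer than 20 cells of a library in a cluster were set aside as rare, and the marker minimum was asked of each library's own cells. The last rule left 31 blood cells unnamed that share a cluster with peritoneal stromal-type cells.

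UMIs of neutrophil-like cells were summed per library and compared in edgeR 4.0.16 (R 4.3.3) with its quasi-likelihood test, TMM scaling and the filterByExpr filter, which kept 12162 genes. The 3 group means were fitted together over 5 libraries, with 2 residual degrees of freedom. The spread of the blood group was assumed to equal that of the peritoneal groups. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Unless stated otherwise, levels of genes are TMM-adjusted CPM as group mean ± SD, and changes are log2 fold changes ± SE. Levels compared between cell classes, subclusters or empty droplets are plain CPM. A fold against a group with 0 UMIs was computed against a floor of 3 UMIs over the group and is given as a lower bound.

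The 18 gene lists, with 418 members of which 416 were among the measured features, were fixed before the data were examined. They were tested with camera in limma 3.58.1 at its preset correlation of 0.01 and adjusted over the 18 lists within each comparison. Camera with an estimated correlation and fry were alternatives. With an estimated correlation no list passed in any comparison, whatever its estimate. The cell cycle list, with an estimate of -0.0114, below the preset, went from adjusted p = 2.09e-13 to 0.244 for 4 h against blood. Antigen presentation, with an estimate of -0.0554, went from 3.74e-06 to 0.465 for day 3 against 4 h. This alternative therefore does not show whether correlated members account for a result. Members are counted as risen or fallen from the adjustment over all tested genes, and the count adjusted over the list alone stands beside it. The genes named were chosen by a rule written before the data were examined. It took, per comparison, the 8 largest rises and the 8 largest falls past the threshold with at least 50 CPM in the higher group and no overlap of the libraries of both groups. It added up to 4 members with the smallest p of each list past its test, and a fixed set that included Arg1, Mrc1, Cd14, Il4ra, Tgfb1 and Ly6g. Mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin, sex-linked and clone-named genes were left out of the rule.

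The test was checked on simulated data in which 100 genes were raised 2-fold and 100 raised 4-fold. It recovered 63% and 94% of them for day 3 against 4 h, 9% and 49% for 4 h against blood, and 9% and 47% for day 3 against blood. Wrong calls were 9 of 166, 3 of 61 and 1 of 57.

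Shares of cells with a UMI were computed after every cell had been thinned at random to 500 UMIs, so that depth did not differ between classes or groups. Intervals of single shares are exact 95% Clopper-Pearson intervals and cover counting error only. A share of 0 is given with the share that 3 cells would make. Group shares were compared with an exact two-sided permutation test. With 2 libraries per group its smallest possible p is 0.333, so it cannot reach 0.05. Gene positions came from the GENCODE M21 annotation on mm10.

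Total depth ranged from 29517859 UMIs in blood to 73023122 in a 4 h library. Called cells numbered 4740 in blood, 7492 and 7193 at 4 h, and 5381 and 3513 at day 3. Barcodes shared between peritoneal libraries exceeded chance, and 1.39% to 3.70% of called cells carried a barcode that was deeper in another peritoneal library. These cells held 0.176% to 0.448% of the UMIs of called cells, stayed in the main values, and were removed in an alternative. The empty-droplet profile may also hold counts from other peritoneal libraries, which was not tested. At day 3 it held Gpnmb at 136 and 163 CPM, where neutrophil-like cells had 0.345 and 0.305 CPM. No other class there exceeded 1.33 CPM, rare cells aside, while 4 h neutrophil-like cells had 911 and 1093 CPM. Values in empty droplets are thus not of free RNA alone. Alternatives covered scaling, test tool, filters, cell and mitochondrial limits, doublets, cell class, free RNA, the replicate number and leaving out each library, and their effect is given in the closing section.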

Results

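The samples came from C57BL/6 mice. Zymosan, a yeast cell wall preparation, causes peritonitis when injected into the abdomen. Blood cells had been taken from naive mice over a density gradient, and peritoneal cells had been isolated with beads against Ly6G, a surface protein of mouse neutrophils, with high purity by flow cytometry per the labels. The series asks how neutrophils that enter the peritoneum late differ from early ones and whether they carry genes of alternative activation, a state best known from macrophages of tissue repair. The naive blood library held 29517859 UMIs. The 4 h libraries held 73023122 and 68247371 UMIs, and the day 3 libraries held 56410917 and 44134262. After removal of likely doublets, 4560 blood cells, 7043 and 6779 cells at 4 h, and 5149 and 3414 cells at day 3 remained. Both blood files held the same library, so blood had 1 independent library and each peritoneal group had 2. Values from blood therefore carry no replicate error.

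Neutrophil-like cells made up nearly all of the peritoneal cells isolated with Ly6G beads at 4 h and fewer at day 3. Their share was 94.3% ± 0.256 (SD, n = 2) at 4 h and 67.5% ± 3.42 (SD, n = 2) at day 3, a difference of 26.8 percentage points. The day 3 share leaves out the unnamed cluster 11, with 6.00% and 6.24% of day 3 cells, whose highest-scoring class was neutrophil. The difference was smaller with such clusters included. B-like cells, with the B cell receptor gene Cd79a at 1142 and 1159 CPM, made up 19.2% and 23.8% of the day 3 libraries and 0.554% and 0.649% of the 4 h libraries. Macrophage-like cells made up 1.49% and 3.16% at 4 h. A cluster with the macrophage genes C1qa, Mrc1 and Retnla, numbered 15 and left unnamed because its cells were shallow, made up 2.72% and 3.16% at day 3. In blood, 70.7% (95% interval 69.38% to 72.04%) of cells were NK-like, with Gzma and Nkg7, and 21.7% (20.5% to 22.9%) were monocyte-like. B-like cells were 0.724%, and no blood cluster was named T-like. How far this 1 library stands for blood mononuclear cells was not tested. Neutrophil-like cells were 110 of 4560 blood cells, or 2.41% (1.99% to 2.90%). As background, most mature neutrophils are lost from blood fractions prepared over such gradients. The exact permutation test of the 4 h and day 3 shares gave p = 0.333, the smallest that 2 against 2 libraries allow. The difference was larger than the spread between replicates, but it fell to 11.1 points with at most 5% mitochondrial UMIs, to 17.8 points with classes read per cell from 300 UMIs, and to 4.76 points when subclusters led by 1 marker of another class were also left out.

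**Figure D1:**
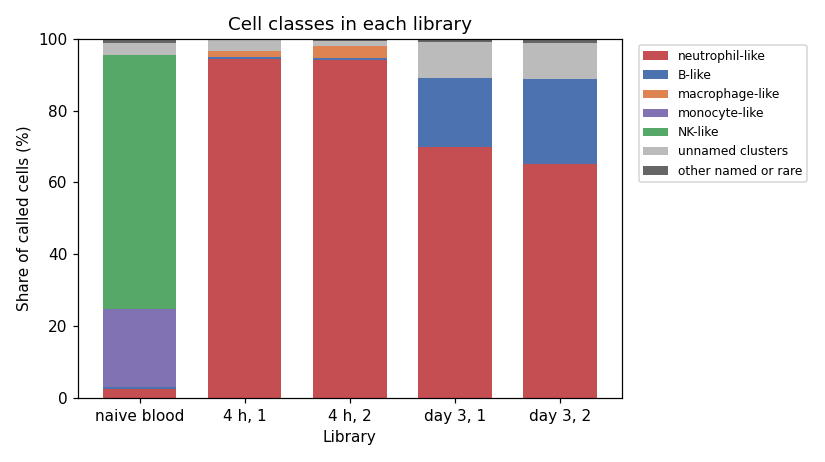
Percent of the cells of each library in each cell class, for the blood library, both 4 h libraries and both day 3 libraries. Neutrophil-like cells made up 94.5% and 94.1% of the 4 h libraries and 69.9% and 65.1% of the day 3 libraries.

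The neutrophil-like sums compared below held 735460 UMIs from 110 cells in blood, 55484988 and 47103699 UMIs from 6654 and 6380 cells at 4 h, and 26093275 and 16398259 UMIs from 3600 and 2222 cells at day 3. Median UMIs per cell were similar, between 5513.5 and 7866. Median genes per cell were 2177 and 2068 at 4 h but 1237 and 1209 at day 3. The 50 most abundant genes took 34.5% and 32.1% of UMIs at 4 h and 47.3% and 48.3% at day 3. In blood, S100a8 and S100a9, the calprotectin genes, alone took 34.0%. TMM scaling therefore applied unequal factors, 1.87 and 1.88 at 4 h and 0.498 and 0.463 at day 3. With library totals in their place, the median log2 fold change of all genes for day 3 against 4 h was -1.98 where TMM gave -0.02, and 1666 genes past the threshold under both had the opposite sign. Directions that depend on this choice are named with the gene or list.

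The first comparison asked how neutrophil-like cells in the peritoneum 4 h after zymosan differed from those in naive blood. Gpnmb, which encodes a lysosomal glycoprotein, stood at 534 ± 65.6 CPM (SD, n = 2) at 4 h and had 0 UMIs in blood, at least 160-fold higher. The C-type lectin gene Clec4n was at least 79.3-fold higher, and the stress cytokine gene Gdf15 at least 51.5-fold higher. Cd14, a co-receptor for microbial products, rose by 6.72 ± 0.75, and Il1b, the gene of interleukin 1 beta, rose 7.74-fold (2.95 ± 0.51). Granule genes of developing neutrophils went the other way: Ngp fell by 13.32 ± 0.39 and Camp, the cathelicidin gene, fell by 12.82 ± 1.15, from 25374 and 30928 CPM in blood. Elane, the neutrophil elastase gene, fell by 10.81 ± 0.54 and the DNA topoisomerase gene Top2a fell by 8.17 ± 0.38. In all, 1136 genes rose and 1111 fell of 12162 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2017 of them by at least 2-fold. At an unadjusted p under 0.05 there were 3841. Adjusted p-values of these named genes lay between 1.89e-05 for Ngp and 0.0154 for Gdf15. The count was 1305 without day 3 replicate 1 and 1385 without day 3 replicate 2, as these libraries inform the spread, and 4608 with the 36 cells of the omitted blood subcluster, which carried the NK genes Gzma and Nkg7, kept in. It was 3954 with library totals, with 3232 genes higher.

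Cell cycle and granule genes were lower at 4 h than in blood. The 110 blood cells formed a subcluster led by granule and maturation genes that included Camp, Fcnb, Ltf, Ngp, Cebpe and Elane. A difference in maturity from these cells cannot be told apart from a change on entering the peritoneum. A further 4, 6 and 4 blood cells lay in neutrophil-like clusters 0, 3 and 9, which held mostly 4 h cells. The rule on rare cells, set after the data were examined, left them out of the comparison. With rare cells kept, blood had 124 neutrophil-like cells. Of 22 cell cycle genes, 0 rose and 21 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.09e-13, and adjusted p = 0.244 with an estimated correlation). Stmn1, a tubulin regulator, fell by 6.22 ± 0.22, and Birc5, the survivin gene, fell by 7.71 ± 0.41. Of 20 specific and gelatinase granule genes, 1 rose and 14 fell, or 1 and 17 adjusted over the list alone (adjusted p = 2.52e-09, and adjusted p = 0.609 with an estimated correlation). Ltf, the lactoferrin gene, fell by 7.88 ± 0.33 and the chitinase-like gene Chil3 fell by 6.89 ± 0.44. Of 9 azurophil granule genes tested, 2 rose and 5 fell, with the same counts adjusted over the list alone (adjusted p = 0.00325, and adjusted p = 0.715 with an estimated correlation). Serpinb1a, a protease inhibitor gene, fell by 7.24 ± 0.31, while Srgn, the proteoglycan core of granules, rose by 2.66 ± 0.32. Ly6g, the gene of the sorting marker, fell by 2.86 ± 0.30, from 729 to 100 ± 35.8 CPM (SD, n = 2). Markers of monocytes moved with these groups: they held 1309 CPM of the neutrophil-like UMIs in blood, 390 and 443 CPM at 4 h, and 4464 CPM of the empty-droplet UMIs in blood. So did markers of progenitors, with 293 CPM in blood and 29.2 and 10.7 CPM at 4 h, beside 27.8 CPM in the empty droplets of blood. Erythroid markers went from 99.6 to 0.0721 and 0.191 CPM, NK markers from 94.1 to 0.0901 and 0.127 CPM, B cell markers from 75.02 to 14.995 and 13.1 CPM, and T cell markers from 34.1 to 1.62 and 4.27 CPM. The chemokine gene Ccl5 fell by 8.21 ± 0.79, and its level of 84.6 CPM in blood neutrophil-like cells stood beside 10024 CPM in empty droplets and 18587 CPM in NK-like cells.

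Lists of lysosomal, interferon, hypoxia and inflammatory genes were higher at 4 h, though most inflammatory genes did not pass by themselves. Of 27 phagocytosis, lysosome and lipid handling genes, 19 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.00086, and adjusted p = 0.688 with an estimated correlation). Lipa, the lysosomal acid lipase gene, rose 19.2-fold (4.27 ± 0.25), the lipid droplet gene Plin2 15.3-fold (3.94 ± 0.23) and Psap, the prosaposin gene, 9.57-fold (3.26 ± 0.26). Of 36 interferon response genes, 18 rose and 1 fell, or 20 and 1 adjusted over the list alone (adjusted p = 0.00299, and adjusted p = 0.827 with an estimated correlation). Slfn5 rose by 4.28 ± 0.38 and Ifi204, a DNA sensor gene, by 2.87 ± 0.31, while Cmpk2 fell by 3.13 ± 0.27. Of 18 hypoxia genes, 11 rose and 0 fell, or 13 and 0 adjusted over the list alone (adjusted p = 0.0241, and adjusted p = 0.827 with an estimated correlation), among them Mif by 6.36 ± 0.41 and Bnip3 by 4.00 ± 0.57. Of 22 NF-kB targets, 11 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.0228), and of 21 inflammatory cytokines and chemokines, 6 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.0282). Both lists had adjusted p = 0.827 with an estimated correlation. Neither passed fry, with adjusted p = 0.0512 for the NF-kB targets and 0.0555 for the inflammatory genes. Sod2 rose by 3.67 ± 0.48 and the chemokine receptor-like gene Ccrl2 by 6.75 ± 0.99. With library totals the hypoxia, NF-kB and inflammatory lists no longer passed (adjusted p = 0.0872, 0.0773 and 0.281). The 4 h libraries differed in the hypoxia gene Bnip3, at 90.1 and 157 CPM, and in neutrophil cluster 8, led by heat shock and hypoxia genes, which held 0.466% and 23.4% of their neutrophil-like cells. Macrophage markers moved with these groups, from 35.5 CPM of the neutrophil-like UMIs in blood to 236 and 226 CPM at 4 h, and dendritic cell markers from 16.4 to 50.6 and 57.4 CPM.

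Of 38 oxidative phosphorylation genes, 0 rose and 10 fell at 4 h, or 1 and 11 adjusted over the list alone (adjusted p = 0.00284, and adjusted p = 0.659 with an estimated correlation), but with library totals 7 rose and 2 fell (adjusted p = 0.347). Ndufa4 fell by 1.36 ± 0.17 and Atp5o fell by 1.26 ± 0.17. Of 19 measurable genes of the alternative activation list, 5 rose and 0 fell, or 5 and 1 adjusted over the list alone, and the list did not pass (adjusted p = 0.0868). It passed with upper quartile factors (4 rose and 0 fell, adjusted p = 0.0486) and did not with library totals (adjusted p = 0.382). It passed fry (adjusted p = 0.0152), but so did glycolysis (fry adjusted p = 0.0398), for which camera gave an adjusted p of 0.677. Its members past the threshold included Pdcd1lg2, an immune checkpoint ligand gene with at least a 20.3-fold rise, and Il4ra, the interleukin 4 receptor gene, which rose by 2.21 ± 0.47. The antigen presentation list did not pass and had a median log2 fold change of -0.12 beside a mean of 1.04. The NADPH oxidase list did not pass and had a median of 1.05 with a test direction of down. Of the neutrophil receptors fixed in advance, Cxcr2 (-0.20 ± 0.30) and Cd101 (-0.55 ± 0.49) did not pass and turned positive with library totals, and Cxcr4 (-0.95 ± 0.30) did not pass.

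The second comparison asked how neutrophil-like cells at day 3 differed from those at 4 h. Clustered without integration, the cells of both times lay in almost wholly separate clusters of this class. Il1b rose 34.7-fold (5.12 ± 0.41), from 1093 ± 475 to 37879 ± 5763 CPM (SD, n = 2 each). Cd14 rose 39.8-fold (5.32 ± 0.42), to 18539 ± 568 CPM, and Il1rn, the gene of the interleukin 1 receptor antagonist, 40.6-fold (5.34 ± 0.45). Cxcl10, an interferon-induced chemokine gene, rose by 10.01 ± 0.56, and Il23a, a subunit of interleukin 23, by 9.76 ± 1.04. Ngp, low at 4 h with 2.48 ± 0.0381 CPM, rose by 11.07 ± 0.36 to 5335 ± 976 CPM. Gpnmb was 782-fold lower and fell by 9.61 ± 0.24, and the antioxidant genes Prdx1 and Gstm1 changed by -5.15 ± 0.21 and -5.10 ± 0.20. Of 12162 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4619 rose and 4197 fell, 6905 of them by at least 2-fold, and 9082 had an unadjusted p under 0.05. Adjusted p-values of these named genes lay between 3.02e-06 for Ngp and 0.000136 for Il23a. With the replicate number as a block, 9075 genes passed. With library totals 1737 genes were higher and 8877 lower at day 3, and the rises of Il1b, Cd14, Il1rn, Cxcl10, Il23a and Ngp and the falls of Gpnmb, Prdx1 and Gstm1 kept their sign. Their sizes depended on the scaling, and the rises of Il1b, Cd14 and Il1rn were smaller with library totals, at log2 fold changes of 3.14, 3.35 and 3.37.

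**Figure D2:**
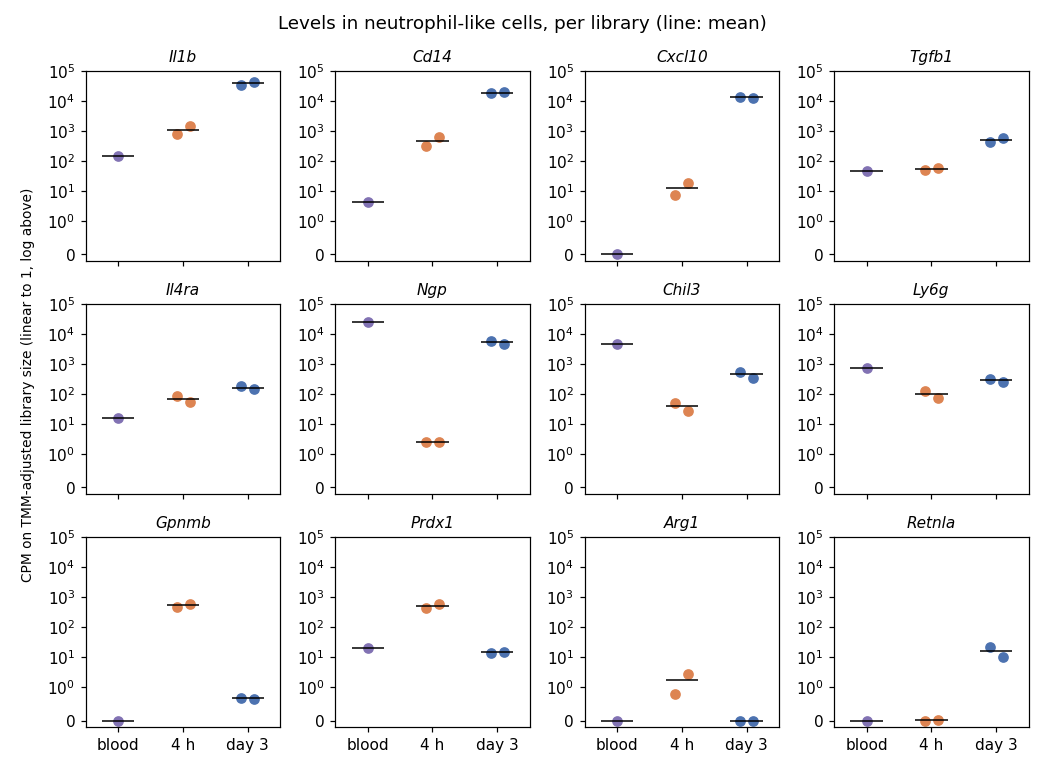
TMM-adjusted CPM of 12 named genes in neutrophil-like cells (y axis, linear to 1 and logarithmic above), by group on the x axis. Points are libraries and lines are group means. Cd14 stood at 4.41 CPM in blood, 465 at 4 h and 18539 at day 3, and Arg1 had 0 UMIs in blood and at day 3.

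Interferon and NF-kB genes rose together at day 3. All 36 interferon response genes tested rose, with the same count adjusted over the list alone (camera adjusted p = 4.01e-13, and adjusted p = 0.465 with an estimated correlation). Cmpk2 rose by 8.77 ± 0.24, Ifi47, an interferon-induced GTPase gene, by 6.73 ± 0.19, and Ifih1, an RNA sensor gene, by 6.66 ± 0.19. With library totals 35 of the 36 rose and 1 fell. The list includes Mx1, whose 17.9 and 16.0 CPM at day 3 stood beside 631 and 644 CPM in empty droplets. Cmpk2 and Ifih1 stood above their empty-droplet levels in both day 3 libraries. All 22 NF-kB targets rose, with the same count adjusted over the list alone (adjusted p = 7.55e-07, and adjusted p = 0.465 with an estimated correlation), among them Nfkb1 by 5.04 ± 0.26 and Birc3 by 4.07 ± 0.21. Of 21 inflammatory cytokines and chemokines, 19 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.000135, and adjusted p = 0.471 with an estimated correlation). Osm, the oncostatin M gene, rose by 7.72 ± 0.77 and Tnf by 5.05 ± 0.62. Of 20 early response genes, which cell preparation also induces, 19 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 7.62e-06, and adjusted p = 0.465 with an estimated correlation), among them Dusp1 by 5.98 ± 0.33. Monocyte markers moved with these groups, from 390 and 443 CPM at 4 h to 2432 and 2290 CPM at day 3, beside 2389 and 2218 CPM in the empty droplets of the day 3 libraries. Erythroid markers went from 0.0721 and 0.191 to 6.36 and 1.65 CPM, and eosinophil markers fell from 62.1 and 41.7 to 10.1 and 9.09 CPM.

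Granule genes, receptors and antigen presentation genes also rose at day 3. Of 20 specific and gelatinase granule genes, 17 rose and 1 fell, or 18 and 1 adjusted over the list alone (adjusted p = 1.53e-05, and adjusted p = 0.465 with an estimated correlation). Itgb2l rose by 7.53 ± 0.19, Olfm4 by 5.35 ± 0.24 and Chil3 by 3.57 ± 0.36, and with library totals 13 rose and 5 fell. Of 24 adhesion and chemoattractant receptors, 19 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.000255, and adjusted p = 0.465 with an estimated correlation). Fpr1 and Fpr2, receptors for formyl peptides, rose by 3.87 ± 0.20 and 3.60 ± 0.19, but with library totals 11 of the 24 rose and 9 fell. Cxcr2 (1.96 ± 0.25) and Cxcr4 (2.17 ± 0.24) rose under TMM and did not pass with library totals (-0.00 and 0.19), nor did Ly6g (1.53 ± 0.26 against -0.43). Cd101 (1.40 ± 0.22) rose under TMM and fell with library totals (-0.57). All 19 antigen presentation and costimulation genes rose, with the same count adjusted over the list alone (adjusted p = 3.74e-06, and adjusted p = 0.465 with an estimated correlation), and with library totals 11 rose and 1 fell. Tap1, the peptide transporter gene, rose by 4.09 ± 0.16. The MHC class 2 genes Cd74 and H2-Aa rose by 5.34 ± 0.21 and 6.29 ± 0.24, but their levels in neutrophil-like cells, 173 and 221 CPM and 25.9 and 31.8 CPM, were below those in the empty droplets of the same libraries, 1594 and 1884 CPM and 548 and 652 CPM. B cell markers in neutrophil-like cells moved with them, from 14.995 and 13.1 CPM at 4 h to 80.0 and 75.7 CPM at day 3, beside 2330 and 2754 CPM in the empty droplets at day 3.

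Among the other lists, 10 of 14 growth and neurotrophic factor genes rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0234, and adjusted p = 0.471 with an estimated correlation), and with library totals 8 rose and 5 fell. Osm (7.72 ± 0.77) and Tgfb1 (3.20 ± 0.18) rose, as did Hbegf (5.06 ± 0.35) and Nrg1 (4.42 ± 0.27), both under 20 CPM. Igf1 had too few UMIs to be tested. Of 21 apoptosis and survival genes, 16 rose and 5 fell, with the same counts adjusted over the list alone (adjusted p = 0.0143, and adjusted p = 0.465 with an estimated correlation), and with library totals 9 rose and 7 fell. Casp4 rose by 4.56 ± 0.20 and Fas, a death receptor gene, by 3.32 ± 0.18. Of 22 unfolded protein and heat shock genes, 12 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.0301, and adjusted p = 0.542 with an estimated correlation), but with library totals 6 rose and 11 fell. Hspa5, an endoplasmic reticulum chaperone gene, rose by 4.52 ± 0.25. Of 38 oxidative phosphorylation genes, 0 rose and 29 fell, with the same counts adjusted over the list alone (adjusted p = 1.8e-05, and adjusted p = 0.465 with an estimated correlation), among them Ndufs3 (-2.36 ± 0.19). Of 27 phagocytosis, lysosome and lipid handling genes, 6 rose and 16 fell, with the same counts adjusted over the list alone (adjusted p = 0.0234, and adjusted p = 0.465 with an estimated correlation), and this list did not pass with library totals (adjusted p = 0.149). Lipa fell by 3.02 ± 0.14 and Plin2 fell by 2.33 ± 0.14, while Lamp2, a lysosomal membrane gene, rose by 2.93 ± 0.17. Macrophage markers in neutrophil-like cells went from 236 and 226 CPM at 4 h to 92.6 and 110 CPM at day 3, in plain CPM. The list was tested under TMM, with factors of 1.87 and 1.88 at 4 h and 0.498 and 0.463 at day 3. On that scale the macrophage markers rose, while in plain CPM they fell. Whether they moved with the list therefore depends on the scaling. The azurophil granule (adjusted p = 0.0664), glycolysis (0.759), hypoxia (0.357), NADPH oxidase (0.0755) and cell cycle (0.0789) lists did not pass.

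**Figure D3:**
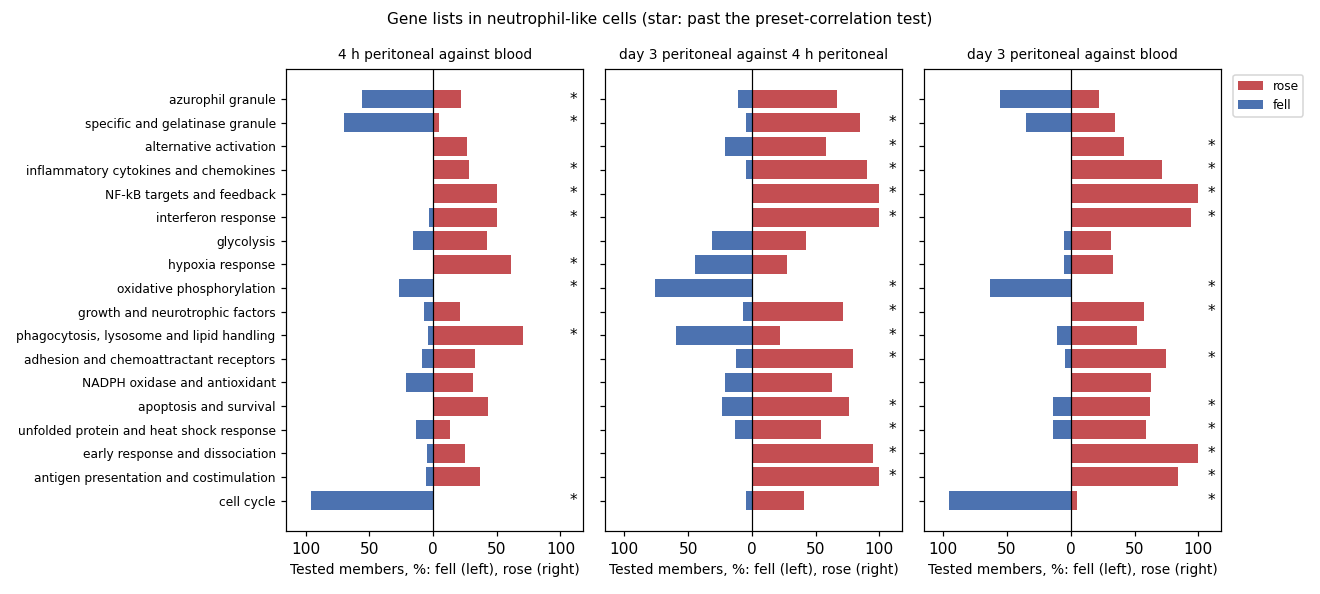
Percent of the tested members of each of 18 gene lists that rose or fell (x axis) in each of the 3 comparisons of neutrophil-like cells, with a star where the list passed camera at its preset correlation. For day 3 against 4 h, 13 lists were past the threshold, and 0 were with an estimated correlation, also where the estimate lay below the preset.

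The alternative activation list addressed the study's question most directly. For day 3 against 4 h, 11 of its 19 tested members rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.0352, adjusted p = 0.465 with an estimated correlation, and fry adjusted p = 0.0126), but with library totals 6 rose and 7 fell. Tgfb1, the gene of transforming growth factor beta 1, rose 9.21-fold (3.20 ± 0.18), from 53.8 ± 4.72 to 496 ± 85.7 CPM (SD, n = 2 each), and Egr2, a transcription factor gene, rose by 5.50 ± 0.40. Il4ra rose by 1.20 ± 0.23 under TMM and fell by 0.75 on the log2 scale with library totals. Irf4 rose by 7.72 ± 0.32, but its 4.60 and 5.49 CPM in day 3 neutrophil-like cells stood beside 156 and 184 CPM in empty droplets. Retnla, a secreted protein gene of alternatively activated macrophages, rose by 10.26 ± 0.63, from 2 UMIs to 360 UMIs, and 7 and 3 cells of the day 3 libraries held 209 and 60 of them. Single cells held 155 of the 280 UMIs of replicate 1 and 46 of the 80 of replicate 2, and the levels of 10.7 and 4.88 CPM stood beside 78.8 and 56.3 CPM in empty droplets. Mrc1, the mannose receptor gene, had 35 UMIs at 4 h and 15 at day 3, and its change of 1.98 ± 0.50 was lost with library totals (0.04). Trem2, a lipid receptor gene, fell by 3.48 and Pdcd1lg2 fell by 2.40.

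Arg1, the arginase 1 gene that marks alternative activation in mouse macrophages, had 0 UMIs in the day 3 neutrophil-like cells. It had 327 UMIs in the 4 h cells, at least 11.7-fold more as CPM (adjusted p = 0.0167, higher in both libraries). After thinning to 500 UMIs per cell, 0 of 3600 and 0 of 2222 day 3 neutrophil-like cells had an Arg1 UMI, which allows shares of up to 0.0833% and 0.135%. At 4 h the shares were 0.0601% and 0.392%, or 0.226% ± 0.235 (SD, n = 2). B-like cells, which should lack Arg1, had 0 of 39 and 0 of 44 at 4 h, which allows up to 7.69% and 6.82%. If all UMIs had come from the empty-droplet profile, 2.26% and 8.77% of 4 h cells would have had one. Arg1 stood at 1.48 and 5.20 CPM in 4 h neutrophil-like cells, beside 45.7 and 183 CPM in empty droplets. That was 3.23% and 2.83% of the empty-droplet level, beside 2.88% and 1.73% for the B cell gene Cd79a. Neutrophil RNA was therefore not the main source of Arg1 in that profile. The Arg1 level at 4 h was near the share seen for this gene of another class, so it gives no evidence that the cells made Arg1. Macrophage-like cells had shares of 50.5% and 53.3%. Without thinning the 4 h shares were 1.20% and 3.43%, at median depths of 7866 and 6947 UMIs in neutrophil-like cells and 28768 and 31428 UMIs in macrophage-like cells.

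Shares of cells with a UMI of the other genes, at the same 500 UMIs per cell, followed plain CPM. Cd14 was seen in 25.02% ± 7.11 (SD, n = 2) of neutrophil-like cells at 4 h and 88.7% ± 0.839 (SD, n = 2) at day 3, beside 5.16% and 3.08% of the day 3 B-like cells. Il1b was seen in 41.8% ± 3.61 and 95.8% ± 1.18 (SD, n = 2 each), beside 12.9% and 6.66% of the day 3 B-like cells. Il4ra was seen in 6.60% ± 2.16 at 4 h and 3.07% ± 0.210 at day 3 (SD, n = 2 each), beside 5.26% and 6.66% of the day 3 B-like cells. At 4 h the B-like cells were few, with Cd14 in 0 of 39 and 0 of 44, Il1b in 1 of each library, and Il4ra in 0 and 4. If all UMIs had come from the empty-droplet profile, Cd14 would have been seen in 42.5% and 55.1% of cells at 4 h and 83.9% and 79.0% at day 3, Il1b in 80.6% and 88.2% and in 99.3% and 99.2%, and Il4ra in 8.23% and 5.28% and in 5.13% and 5.15%. That profile also holds RNA of neutrophils, so for these genes it does not separate free RNA from RNA of the cells. Mrc1 was seen in 1 cell of each 4 h library and 0 cells of each day 3 library. The exact permutation test of 2 against 2 libraries cannot give a p under 0.333 for these shares.

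The alternative activation list was also read across subclusters of neutrophil-like cells, which had been formed with its members left out. At day 3 there were 3 subclusters. The subcluster led by Cxcl1, Nr4a3 and Ptgs2 held 1135 and 1082 CPM of the list, that led by Gbp5 and Cxcl10 held 861 and 812 CPM, and that led by the granule genes Ngp, Cd177 and Mmp8 held 492 and 408 CPM. The highest over the lowest was 2.48 ± 0.246 (SD, n = 2). Tgfb1, a member of the list and so part of these sums, followed the same order, with 403 and 409, 273 and 286, and 101 and 93.7 CPM. Il4ra went in the opposite order, with 44.6 and 44.9, 68.3 and 64.0, and 126 and 89.4 CPM, and Retnla stood at 4.22 and 3.29, 3.87 and 0.598, and 17.9 and 9.99 CPM. Single cells held 155 of the 280 and 46 of the 80 Retnla UMIs of the day 3 libraries. Only the granule gene subcluster had enough Retnla UMIs to contain them, so its Retnla level rests largely on 1 cell per library. Arg1 had 0 UMIs in each of the 3. At 4 h, the list ranged from 392 and 431 CPM in the subcluster led by histone genes to 962 and 1040 CPM in that led by G0s2, Hspa1a and Pfkfb3, which held 9 cells of replicate 1 and 619 of replicate 2. The subcluster led by Gpnmb, Gstm1 and Gadd45g held 943 and 1005 CPM, that led by Prok2 and Cd48 held 848 and 900 CPM, and that led by Hspa1b and Hspa1a held 733 and 887 CPM, with 24 and 898 cells. These are values with no test.

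The third comparison asked how day 3 neutrophil-like cells differed from those in naive blood. Cxcl10 had 0 UMIs in blood and was at least 3971-fold higher at day 3, the early response gene Nr4a3 at least 983-fold and Il1a, the gene of interleukin 1 alpha, at least 828-fold. Cd14 rose by 12.04 ± 0.84, Il1b by 8.07 ± 0.66 and Il1rn by 8.16 ± 0.72. The primary granule genes Elane and Prtn3 changed by -9.06 ± 0.61 and -8.84 ± 1.01, and Cebpe, a transcription factor gene of granule formation, fell by 6.47 ± 0.23. Chil3 fell by 3.32 ± 0.39 and Ly6g fell by 1.33 ± 0.30. As at 4 h, such falls cannot be told apart from a difference in maturity from the blood cells. In all, 2885 genes rose and 1684 fell of 12162 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4152 of them by at least 2-fold, with 5524 at an unadjusted p under 0.05. Adjusted p-values of these named genes lay between 7.35e-05 for Cebpe and 0.0171 for Nr4a3. The count was 7077 with the omitted blood subcluster kept in. With library totals 1344 genes were higher and 4041 lower.

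Not every list that had risen at day 3 against 4 h stood high against blood. Of 20 specific and gelatinase granule genes, 7 rose and 7 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.277, and adjusted p = 0.656 with an estimated correlation). Of 36 interferon response genes, 34 rose and 0 fell (camera adjusted p = 3.98e-10, and adjusted p = 0.473 with an estimated correlation), all 22 NF-kB targets rose (adjusted p = 1.15e-05, and adjusted p = 0.55 with an estimated correlation), and all 20 early response genes rose (adjusted p = 0.000101, and adjusted p = 0.55 with an estimated correlation). These 3 lists had the same counts adjusted over the list alone. Slfn5 rose by 8.87 ± 0.38, Isg20 by 7.69 ± 0.34, Relb by 6.36 ± 0.37 and Dusp1 by 6.54 ± 0.47. Of 21 inflammatory genes, 15 rose and 0 fell, or 18 and 0 adjusted over the list alone (adjusted p = 0.000187, and adjusted p = 0.55 with an estimated correlation). Of 24 adhesion and chemoattractant receptors, 18 rose and 1 fell, or 20 and 1 adjusted over the list alone (adjusted p = 0.000385, and adjusted p = 0.55 with an estimated correlation). Ptafr, the receptor gene for platelet-activating factor, rose by 5.97 ± 0.35 and C5ar1, a complement receptor gene, by 4.18 ± 0.28. Of 19 antigen presentation genes, 16 rose and 0 fell (adjusted p = 0.00594, and adjusted p = 0.473 with an estimated correlation), with Tap1 up by 5.65 ± 0.28 and H2-K1 by 4.25 ± 0.29, the latter at 1675 and 1515 CPM beside 3163 and 2607 CPM in empty droplets. Of 21 apoptosis genes, 13 rose and 3 fell (adjusted p = 0.0365, and adjusted p = 0.55 with an estimated correlation), with Pim1, a survival kinase gene, up by 6.24 ± 0.36. The last 2 lists had the same counts adjusted over the list alone.

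Of 19 alternative activation genes, 8 rose and 0 fell against blood, with the same counts adjusted over the list alone (adjusted p = 0.00558, adjusted p = 0.55 with an estimated correlation, and fry adjusted p = 0.00522), and with library totals 7 rose and 0 fell. Tgm2, the tissue transglutaminase gene, rose by 7.83 ± 0.52, Tgfb1 by 3.39 ± 0.28 and Fcgr2b, the inhibitory Fc receptor gene, by 2.53 ± 0.30. The 37.1 and 36.2 CPM of Fcgr2b at day 3 stood beside 270 and 273 CPM in empty droplets and 464 and 481 CPM in cluster 15. Il4ra rose 10.6-fold (3.41 ± 0.46). Retnla, with 0 UMIs in blood, was at least 5.29-fold higher and did not pass with library totals (adjusted p = 0.0965). Arg1 had 0 UMIs in both groups, and Mrc1 had 0 in blood and 15 at day 3. Of 14 growth factor genes, 8 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.0486, and adjusted p = 0.576 with an estimated correlation), among them Thbs1, the thrombospondin 1 gene, by 7.08 ± 0.95 and Spp1, the osteopontin gene, by 8.70 ± 1.08. Of 22 unfolded protein and heat shock genes, 13 rose and 3 fell, or 14 and 3 adjusted over the list alone (adjusted p = 0.0486, and adjusted p = 0.615 with an estimated correlation), with Hspa5 up by 4.13 ± 0.35. Of 38 oxidative phosphorylation genes, 0 rose and 24 fell, or 0 and 26 adjusted over the list alone (adjusted p = 2.21e-08, and adjusted p = 0.371 with an estimated correlation), with Ndufa4 lower (-2.89 ± 0.18). Of 22 cell cycle genes, 1 rose and 21 fell, with the same counts adjusted over the list alone (adjusted p = 3.2e-09, and adjusted p = 0.366 with an estimated correlation), with Tubb5 lower (-4.41 ± 0.21). Cxcr2 (1.76 ± 0.33) and Cxcr4 (1.22 ± 0.32) rose under TMM and did not pass with library totals. Markers of other classes moved as well: those of monocytes held 1309 CPM in the blood neutrophil-like cells and 2432 and 2290 CPM at day 3, those of macrophages 35.5 against 92.6 and 110 CPM, those of dendritic cells 16.4 against 43.5 and 37.5 CPM, and those of progenitors 293 against 18.3 and 14.1 CPM. Erythroid markers held 99.6 against 6.36 and 1.65 CPM, NK markers 94.1 against 0.268 and 0 CPM, eosinophil markers 54.6 against 10.1 and 9.09 CPM, and T cell markers 34.1 against 7.43 and 6.83 CPM, while B cell markers held 75.02 against 80.0 and 75.7 CPM. These marker levels are plain CPM. With the TMM factors of 1.23 in blood and 0.498 and 0.463 at day 3, B cell markers were higher at day 3.

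The main genes were located on mm10 as follows. Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139, minus strand. Cd14 (ENSMUSG00000051439) lies on chromosome 18 from 36725067 to 36726798, minus strand. Arg1 (ENSMUSG00000019987) lies on chromosome 10 from 24915221 to 24927484, minus strand. Tgfb1 (ENSMUSG00000002603) lies on chromosome 7 from 25687002 to 25705077, plus strand, and Il4ra (ENSMUSG00000030748) on the same chromosome from 125552120 to 125579474, plus strand. Ngp (ENSMUSG00000032484) lies on chromosome 9 from 110419747 to 110423012, plus strand, and Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929, plus strand. All 7 are annotated as protein-coding genes.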

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

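All tests of the 3 patterns below were chosen only after the result had been seen, except the test of heat or handling stress over a whole 4 h library and the test of summed Mrc1 and Retnla UMIs. The latter had been planned, and a test per cell chosen later was set beside it.

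B-like cells made up 19.2% and 23.8% of the day 3 libraries, although these had been isolated with beads against Ly6G, and drew attention because the comparisons of neutrophil-like cells do not use them. Swapped barcodes from other peritoneal libraries accounted for at most 0.123% of them. Droplets with a B cell and a neutrophil were argued against by S100a8 and S100a9 together, which in B-like cells reached at most 2.24% of their level in neutrophil-like cells. Ly6g of their own was argued against as well, since Ly6g in B-like cells reached at most 0.0260 of its level in empty droplets. Carry-over of unselected B cells through the beads, and a higher number of B cells in the peritoneum at day 3 than at 4 h, were not tested and stay open.

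Retnla in day 3 neutrophil-like cells stood out because the same libraries held another cell group rich in it: 47.1% and 46.3% of cluster 15 cells had a Retnla UMI after thinning, a signal in cells that no comparison uses. Reads of the paralog Retnlg were argued against, since the 4 h cells held 1.41% of the Retnla UMIs that the day 3 ratio to Retnlg predicted, and for the 7 and 3 cells with 3 or more Retnla UMIs free RNA was argued against by their number, at least 26.3 times that of a Poisson spread. In the other cells, Retnla over Mrc1 was at most 1.92 times the ratio of the empty droplets (95% interval 0.988 to 4.19), which is consistent with free RNA as a source of those UMIs. For the 7 and 3 cells, the planned test spoke against droplets shared with a cluster 15 cell, with an upper bound of 0.0634 for Mrc1 over Retnla where cluster 15 had 0.103 and 0.233, but single cells held 155 and 46 of their 209 and 60 Retnla UMIs, which are not independent. Counted per cell, 0 held an Mrc1 UMI, with chances of 0.0499 and 0.0193 from cluster 15 cells but up to 0.272 with the error of their shares, so shared droplets stay open.

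Neutrophil cluster 8, led by the heat shock genes Hspa1a and Hspa1b and the hypoxia gene Ero1l, held 1492 cells of 4 h replicate 2 and 31 of 4 h replicate 1. Lower depth was argued against by a median UMI count 0.874 times that of the library's other neutrophil-like cells, and macrophage RNA by Arg1, C1qa and C1qb, which together were 1.09 times as high. Heat or handling stress over the whole library could not be excluded. Summed heat shock genes of replicate 2 over replicate 1 were 1.30 in neutrophil-like cells outside the cluster, 1.72 in macrophage-like cells and 0.610 in B-like cells, values that go in both directions. A difference between the replicates was not tested and stays open.

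Macrophage-like cells at 4 h had an Arg1 UMI after thinning in 50.5% and 53.3% of cells, a signal in cells that the comparisons do not use.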

How the results depend on the processing

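Chosen after the data were seen were library totals, both blood files kept apart, swapped barcodes removed, the alternatives on unnamed clusters, rare cells and subclusters, and the 4 h fit without cluster 8; the rest were planned. Of 182 alternatives to 9 results, 160 kept the value within the spread between replicates or within 1.5 times the count, and 22 moved it. The cause of the moves was not tested, but for the neutrophil-like share cell numbers show part of it. At most 5% mitochondrial UMIs kept 3587 and 2216 of the 3600 and 2222 day 3 neutrophil-like cells. The day 3 B-like cluster 6 had a median of 6.85%, above that limit. Leaving out subclusters led by 1 foreign marker took 4 h cells, from 6654 and 6380 to 4919 and 5062, and left day 3 at 3600 and 2222. The gap in neutrophil-like share (26.8 points) was 11.1 with at most 5% mitochondrial UMIs, 20.1 with cells classed singly, 20.7 with neutrophil-type unnamed clusters included, 4.76 with subclusters led by 1 foreign marker left out, and 17.8 with cells classed singly from 300 UMIs (24.4 to 29.2 with a library left out). The Arg1 gap (0.226 points) was 2.32 without thinning, 0.420 with cells classed singly, and 0.0601 to 0.392 with a library left out. Genes for 4 h against blood (2247) were 7110 in all called cells, 4608 with no subcluster left out, 3954 with library totals, 4432 with both blood files apart, and 1305 (without day 3 replicate 1; 1385 without day 3 replicate 2) to 3141 with a library left out. Its lists (9) were 14 with no subcluster left out, 5 with library totals, 0 with an estimated correlation, and 6 to 11 with a library left out. Genes for day 3 against 4 h (8816) stayed between 7338 and 10614, though library totals gave 1737 higher and 8877 lower where TMM gave 4619 and 4197, with 7338 to 8820 when a library was left out. Its lists (13) were 0 with an estimated correlation and 11 to 13 with a library left out. Genes for day 3 against blood (4569) were 7489 in all called cells, 7077 with no subcluster left out, and 3833 to 5122 with a library left out, and its lists (12) were 0 with an estimated correlation and 9 to 12 with a library left out. A library left alone in its group was assumed to vary like the others. With upper quartile factors 40.3%, 39.3% and 41.2% of the genes called in the 3 comparisons were higher, against 50.6%, 52.4% and 63.1%.

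With the replicate number as a block, 9075 genes and 13 lists passed for day 3 against 4 h. The deviations of replicate 1 from its group mean correlated across genes at 0.0925 between both times, so the numbers gave little sign of pairing. No paired analysis was possible for the comparisons with blood because its 2 files hold 1 library. The spread of the alternative activation list without subclusters rich in monocyte or macrophage markers gave no value, since all 3 day 3 subclusters were removed. Depth limits most the blood group, with 110 neutrophil-like cells.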

Other observations

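The values below come from tables read after the data had been examined, and no test was run on them. Macrophage-like cells at 4 h carried the acute phase gene Saa3 at 9698 and 8582 CPM, the fibronectin gene Fn1 at 2793 and 2841 CPM, the platelet factor gene Pf4 at 1472 and 1190 CPM, and Cd5l, a gene of resident macrophages, at 517 and 628 CPM. Arg1 stood at 1845 and 2582 CPM, Mrc1 at 173 and 127 CPM and Igf1 at 72.89 and 72.04 CPM in these 105 and 214 cells, whereas Retnla stood at 1.78 and 18.8 CPM. Gata6, a transcription factor gene of resident peritoneal macrophages, was low at 4.62 and 2.80 CPM.

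At day 3, some genes of alternative activation stood high in cluster 15 and others did not. Its 140 and 108 cells carried Retnla at 6628 and 4266 CPM, the eosinophil-attracting chemokine gene Ccl24 at 1305 and 2259 CPM, Mrc1 at 685 and 992 CPM and Il10 at 524 and 121 CPM, with 0 Arg1 UMIs. Chil3 stood at 67.8 and 8.43 CPM there, below the 281 and 165 CPM of the day 3 neutrophil-like cells. The day 3 B-like cells carried Ighm at 4411 and 4541 CPM and Ms4a1 at 686 and 717 CPM, with Ighd at 228 and 205 CPM, and the B-1 cell gene Cd5 was low at 1.52 and 1.84 CPM. Zbtb32 stood at 50.9 and 46.2 CPM, Spn at 7.29 and 9.05 CPM and Cr2 at 6.24 and 5.98 CPM. The type of these B-like cells was not tested. A further 6.00% and 6.24% of day 3 cells formed the unnamed cluster 11, with a median of 811 and 841 UMIs, S100a8 at 112054 and 115858 CPM and Il1b at 10684 and 13119 CPM. Cluster 13, with few UMIs per cell, held 3.02% and 1.53% of the 4 h cells and 1.20% and 0.615% of the day 3 cells. Pou2af1, Il2ra and Ly6a were among its leading genes and among those of the day 3 B-like cluster 6. Median mitochondrial shares were 6.88% and 6.85%. Its 213 and 104 cells at 4 h had medians of 636 and 616.5 UMIs. Called 4 h cells with a barcode deeper in another peritoneal library numbered 277 and 139, with medians of 647 and 653 UMIs. Without such barcodes, 6636 of 6654 and 6362 of 6380 neutrophil-like cells remained at 4 h, so few of these cells were neutrophil-like. Whether the others are the cells of cluster 13 was not tested.

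In blood, the monocyte-like cells carried Ly6c2 at 872 CPM, Ccr2 at 793 CPM and Cx3cr1 at 316 CPM. The unnamed cluster 19, 2.57% of blood cells, was led by Cd209a, Clec10a and H2-Ab1. NK-like cells carried Gzma at 13439 CPM and Ccl5 at 18587 CPM, with the T cell gene Cd3e at 1.16 CPM. Markers of NK cells in the blood neutrophil-like cells reached 94.1 CPM, or 0.406% of their level in NK-like cells, and B cell markers in the day 3 neutrophil-like cells reached 0.979% and 0.903% of their level in B-like cells.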
